A study of Mus musculus with 8 samples.

How the data were processed

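RNA was sequenced from 2 sorted bone marrow populations of mice, pre-Baso and basophils, each from control animals and from animals with a floxed Nfil3 gene removed. The 8 libraries fall into 4 groups of 2, which the series' design text calls biological duplicates. Per the labels' protocols, libraries were made from total RNA with a SMARTER kit for mRNA sequencing. Reads were aligned with HISAT2 (version not given) to mm10, per the submitters' processing notes, and transcripts were quantified by StringTie 2.1.4 against Ensembl release 101 annotation in the mode that estimates annotated transcripts only, per the file headers. The quantification command names no strand option, so a gene and its antisense partner cannot be told apart.

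Each library's table lists 142699 transcripts with TPM (a length-scaled share of all transcripts), FPKM and mean per-base read coverage, per the file headers. The tables hold no read counts. Summed coverage times length gave 271.7 to 398 megabases assigned per library. Reads of a few annotated small RNA and ribosomal genes took most of the TPM: genes annotated as microRNA took 57.4% to 62.8%, of which Gm23935 alone took 30.3% to 33.0%, while protein-coding genes took 18.7% to 22.4%. By assigned bases, protein-coding genes took 52.9% to 57.2% and ribosomal RNA 28.9% to 33.1%. A TPM of 1 therefore stands for a larger share of the messenger RNA than in a library without these RNAs.

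Gene TPM is the sum over a gene's transcripts. Of 55487 genes, 45578 had a name in the files, 9814 took theirs from a reference table by identifier, and 95 had none. The 12511 genes with a TPM of at least 1 in at least 2 libraries were tested on log2(TPM + 1), a scale that understates changes of genes near a TPM of 1. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 8 libraries, which leaves 4 residual degrees of freedom, with moderation by the trend of the variance. The 6 contrasts tested were genotype within each population, its mean over both, the change from pre-Baso to basophils within each genotype, and the difference of the genotype effect between populations. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene was called at an adjusted p under 0.05. Log2 changes are given with their standard errors (SE). Adjusted p-values without another name are from limma.

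Lists of genes were fixed before the data were examined: 31 lists of basophil functions, cell cycle, metabolism and markers of other cell types. Of these, 29 had at least 5 tested members. The mast cell list had 2 tested members and the T and NK cell list 4, so they were not tested. The camera test of limma compared each list with all other genes, two-sided, with a preset correlation between genes of 0.01 and adjustment over the lists. No list passed the threshold in any contrast when the correlation was estimated from the residuals. Counts of genes in a list are given over all genes tested and, where stated, adjusted over the list alone. Nfil3 itself was tested by an exact permutation test, two-sided, over all 70 splits of 4 against 4 libraries.

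Genes were named by a rule fixed before the data were examined. It allows Nfil3 in every contrast. Per contrast it allows the 12 highest and 12 lowest log2 changes among called genes with a mean TPM of at least 5 in the higher group and no overlap between libraries, leaving out systematic names, mitochondrial genes, pseudogenes and receptor segments. Where fewer than 5 genes pass, it allows the 10 genes with the smallest p, as values only. It also allows up to 4 members of a list with the smallest adjusted p and the called members of the basophil identity, Fc epsilon RI, cytokine, clock, apoptosis and transcription factor lists. Last, it allows the most abundant markers of other cell types. A gene outside the rule is said to be so.

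The fit was tested on simulated data, with 100 genes changed by a log2 of 1 and 100 by a log2 of 2 among 12511. Changed genes were drawn from those with a mean log2(TPM + 1) of at least 2. For changes of genes below that level the fit was not tested. In the simulated pre-Baso genotype contrast it recovered 65% and 98%, with 5.23% false calls. In the simulated basophil genotype contrast it recovered 62% and 96%, with 4.24% false calls, and in the simulated control maturation contrast 60% and 100%, with 5.88% false calls. Of 5 lists shifted by a log2 of 0.5, camera called 5 in each simulation, and it called 0 of 17, 0 of 20 and 1 of 13 untouched lists. The simulated genes varied independently, so the simulation could not test camera under correlation between genes. In the data the estimated correlation was 0.56 for genes of the G2 and M phases and 0.73 for histone genes. Alternatives tried were other scalings, FPKM, other pseudocounts and filters, robust moderation, a fit of the compared groups alone, a replicate block, removal of mitochondrial and ribosomal protein genes, and leaving out each library in turn. Rescaling to protein-coding genes and a test of the mean score of each list were added after the data were seen. Figures were drawn with matplotlib 3.10.9 from values handled in pandas 2.3.3 under Python 3.11.15.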

Results

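Gene expression was measured by RNA sequencing in 2 mouse bone marrow populations, pre-Baso and basophils. They came from control mice and from mice with a floxed Nfil3 gene removed, called deficient here. Nfil3 is a transcription factor of the basic leucine zipper family. Its loss was measured in these sorted cells only. Both populations were sorted as lineage-negative CD200R3-positive cells, pre-Baso by high and basophils by intermediate staining for the IgE receptor alpha chain. Each of the 4 groups held 2 libraries, which the design text calls biological duplicates, with 271.7 to 398 assigned megabases per library. Correlations of log2(TPM + 1) across genes were 0.962 to 0.979 between replicates, 0.956 to 0.974 between genotypes of 1 population and 0.896 to 0.953 between populations. The first principal component held 55.3% of the variance and separated the populations: pre-Baso libraries lay between -38.4 and -29.5, control basophils at 39.4 and 48.6 and Nfil3-deficient basophils at 15.8 and 29.5.

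Nfil3 was low in every library of deficient mice. In pre-Baso its mean fell from 7.13 ± 0.734 TPM (SD, n = 2) in controls to 0.312 ± 0.441 TPM (SD, n = 2), and in basophils from 21.5 ± 1.41 to 1.09 ± 0.332 TPM. Nfil3 (ENSMUSG00000056749) lies on chromosome 13 from 52967209 to 52981073 in mm10 and has 2 annotated exons. Coverage of exon 2, from 52967209 to 52969021, was 4.29 to 12.04 in the 4 control libraries and 0 to 0.191 in the 4 deficient libraries. Exon 1 had coverage of 1.20 to 2.87 in controls and 0 to 5.62 in deficient libraries, so the loss lay in exon 2. The log2 difference over all 8 libraries was -3.05, with p = 0.0286 in the exact permutation test, the smallest p that 4 against 4 libraries allow. The test permuted libraries without regard to population. Only 18 splits into 4 and 4 are balanced within the populations, too few for a p under 0.05.

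The comparison of genotypes in pre-Baso asks which genes of these precursors differ between control and deficient mice. The labels do not name the Cre driver that removed Nfil3, so a difference between the mice need not stem from Nfil3. Mcpt8, the basophil-specific granule protease, was almost absent from deficient pre-Baso: it fell from 7066 ± 1162 TPM (SD, n = 2) to 5.06 ± 1.39 TPM, a log2 change of -10.20 ± 0.24 (SE; limma adjusted p = 5.56e-07). Rnase12, a member of the ribonuclease A family, fell from 102 ± 13.7 to 2.68 ± 0.188 TPM (log2 change -4.80 ± 0.18, adjusted p = 1.57e-05). Lgals3, which encodes galectin-3, rose from 89.9 ± 9.34 to 198 ± 15.7 TPM (1.13 ± 0.14, adjusted p = 0.0404). Rprl3, a copy of the RNA component of RNase P, rose from 0.211 ± 0.103 to 68.4 ± 11.8 TPM (5.83 ± 0.39, adjusted p = 0.00101), while Rpph1, the main RNase P RNA gene and here outside the naming rule, had means of 704 and 235 TPM in control and deficient pre-Baso (-1.58 ± 0.22, adjusted p = 0.0877).

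In all, 8 of 12511 genes were called in pre-Baso, 4 higher and 4 lower in deficient cells, and 548 had an unadjusted p under 0.05, where 626 would be expected by chance. Nfil3 was among them (-2.67 ± 0.25, adjusted p = 0.00896). The Nfil3 call ended without the first control pre-Baso library (adjusted p = 0.165) and without the second (adjusted p = 0.136). It also ended with a pseudocount of 0.1 (adjusted p = 0.175), without a filter on low values (adjusted p = 0.0564), with protein-coding genes only (adjusted p = 0.121) and with only the compared groups fitted (adjusted p = 0.0942). The Lgals3 call ended when any of the 8 libraries was left out, with adjusted p from 0.071 to 0.295. Of the called genes, 4 lie within 10 Mb of Mcpt8 on chromosome 14, among them Mcpt8 itself: the others were Rnase12, Lgals3 and Gm43305, the last named after its values were seen.

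Basophil identity genes other than Mcpt8 were not called between genotypes in pre-Baso, which with 2 libraries per group does not show equal levels. Of 28 tested basophil identity genes 5 had a positive change. Over all genes 0 were called higher and 1 lower, Mcpt8, and adjusted over the list alone the counts were again 0 and 1. The IgE receptor alpha chain gene Fcer1a had means of 852 ± 152 and 629 ± 116 TPM, the protease gene Prss34 22420.1 ± 3677 and 20564 ± 2248 TPM, the mast cell carboxypeptidase gene Cpa3 363 ± 20.9 and 338 ± 13.8 TPM, and Gata2 230.3 ± 21.8 and 201 ± 45.2 TPM in control and deficient pre-Baso (SD, n = 2), and these 4 genes were picked outside the naming rule. The identity list, which includes Mcpt8 and was not tested without it, fell slightly by camera (median log2 change -0.09, adjusted p = 0.0231, and adjusted p = 0.863 with an estimated correlation). Its call ended without the second control (median 0.02, adjusted p = 0.477) and without the first deficient pre-Baso library (median -0.005, adjusted p = 0.483). The median was -0.25 and -0.21 without the other 2 pre-Baso libraries.

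In pre-Baso 10 lists were called by camera, 6 higher and 4 lower. Ribosomal protein genes were called higher in deficient cells, with 72 of 80 above 0 and a median of 0.15 (adjusted p = 1.28e-11). Histone genes followed with 59 of 62 above 0 and a median of 0.22 (adjusted p = 2.86e-10), then nuclear genes of the respiratory chain with 60 of 75 above 0 and a median of 0.14 (adjusted p = 1.87e-06), and cytokines with 11 of 14 above 0 and a median of 0.27 (adjusted p = 0.00739). Lineage transcription factors stood lower (median -0.16, adjusted p = 0.0154), as did clock genes (median -0.15, adjusted p = 0.0231), which include Nfil3. Not 1 member of the ribosomal, histone, respiratory chain, cytokine or transcription factor lists was called over all genes or adjusted over the list alone. With an estimated correlation each of these lists had adjusted p = 0.863. The libraries of the 2 genotypes overlapped in the mean log2(TPM + 1) of the first 3 lists. Ribosomal genes had 7.67 and 7.88 in control and 8.02 and 7.75 in deficient pre-Baso libraries. Histone genes had 5.19 and 5.54 against 5.71 and 5.43, and respiratory chain genes 5.96 and 6.23 against 6.30 and 6.11. Without the first deficient pre-Baso library the histone (adjusted p = 0.062), respiratory chain (adjusted p = 0.187), transcription factor (adjusted p = 0.975) and clock (adjusted p = 0.168) calls ended, and without the second the cytokine call ended (adjusted p = 0.0941). Without the first control pre-Baso library the transcription factor (adjusted p = 0.0772) and clock (adjusted p = 0.129) calls ended.

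The medians of these lists in pre-Baso also depended on single libraries. Without the first control pre-Baso library the median was 0.06 for ribosomal, 0.03 for histone, -0.04 for respiratory chain and 0.02 for cytokine genes. Without the second it was 0.25, 0.40 and 0.29 for the first 3 and -0.04 for transcription factors. Without the first deficient pre-Baso library it was 0.07 for ribosomal, 0.07 for histone, 0.04 for respiratory chain, 0.03 for transcription factor and -0.08 for clock genes. Without the second deficient library these values were 0.25, 0.34, 0.22, -0.35 and -0.28.

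The other 3 lists called in pre-Baso were the unfolded protein response, lower with a median of -0.14 (adjusted p = 0.0429), and monocyte and macrophage markers and B and plasma cell markers, higher with medians of 0.17 (adjusted p = 0.0429) and 0.53 (adjusted p = 0.0479). With an estimated correlation each had adjusted p = 0.863. Without the second control pre-Baso library each of these 3 calls ended (adjusted p = 0.427), with medians of 0.04 for the unfolded protein response and 0.25 for monocyte markers. The unfolded protein response and monocyte calls also ended without the second deficient pre-Baso library (adjusted p = 0.839 and 0.277), where the first had a median of -0.08 and B cell markers 0.98. The B cell call ended without the first deficient library (median 0.09, adjusted p = 0.678), where monocyte markers had a median of 0.26 and the unfolded protein response -0.25. Without the first control pre-Baso library the latter was -0.34.

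**Figure D1:**
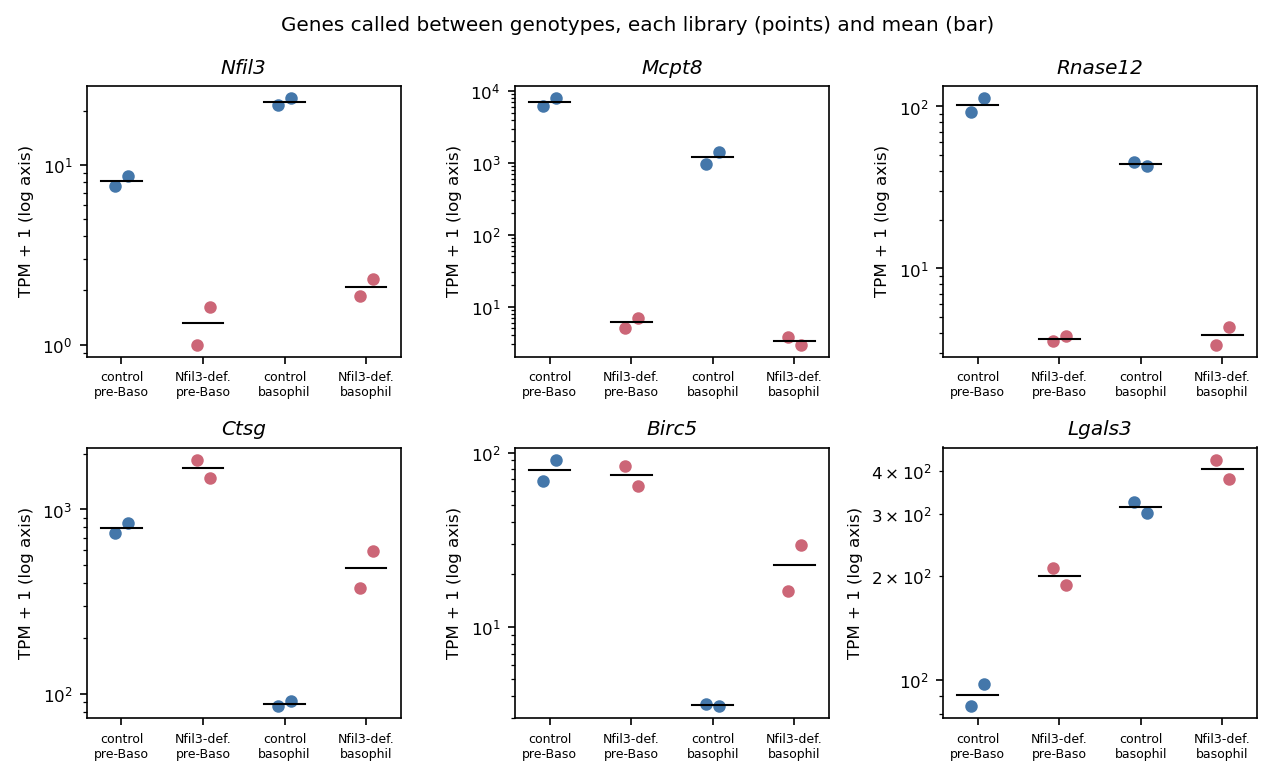
Levels of 6 genes in each library, as TPM + 1 on a log axis, for the 4 groups on the horizontal axis; points are libraries (2 per group) and bars their means. Nfil3, Mcpt8 and Rnase12 lie far lower in both deficient groups, while Ctsg, Birc5 and Lgals3 are higher in at least 1 of them.

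In basophils of deficient mice Mcpt8 and Rnase12 were again nearly absent, and Ctsg and Birc5 were higher than in controls. Mcpt8 fell from 1185 ± 305 to 2.35 ± 0.536 TPM (SD, n = 2; log2 change -8.45 ± 0.24, adjusted p = 2.65e-06) and Rnase12 from 43.4 ± 1.63 to 2.88 ± 0.69 TPM (-3.52 ± 0.18, adjusted p = 0.000198). Ctsg, which encodes the granule protease cathepsin G, rose from 87.8 ± 3.73 to 484 ± 154 TPM (2.41 ± 0.21, adjusted p = 0.00505). Ctsg lies 0.0177 Mb from Mcpt8, and in pre-Baso, where it was not called, it had means of 793 and 1671 TPM (1.07 ± 0.21, adjusted p = 0.404). Birc5, which encodes survivin, a protein of mitosis, rose from 2.55 ± 0.07 to 21.7 ± 9.41 TPM (2.61 ± 0.29, adjusted p = 0.0231). Rprl3 rose from 0.47 ± 0.664 to 84.6 ± 42.2 TPM (5.85 ± 0.39, adjusted p = 0.000983).

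Over all genes 7 were called in basophils, 4 higher and 3 lower, Nfil3 among them (-3.44 ± 0.25, adjusted p = 0.00151), and 1065 had an unadjusted p under 0.05. Without the first control basophil library 17 genes were called. The Birc5 call ended when either pre-Baso library of either genotype, the second control basophil library or the second deficient basophil library was left out, with adjusted p from 0.0586 to 0.0693. With only the compared groups fitted, the calls of Birc5, Ctsg and Rprl3 ended (adjusted p = 0.279, 0.222 and 0.175). Without a filter on low values those of Birc5 and Ctsg ended (adjusted p = 0.131 and 0.0659), and a pseudocount of 5 ended that of Birc5 (adjusted p = 0.0696). The Nfil3 call ended with a pseudocount of 0.1 (adjusted p = 0.164) and with protein-coding genes only (adjusted p = 0.0627). Of the 7, 3 lie within 10 Mb of Mcpt8 when Mcpt8 itself is counted, the others being Rnase12 and Ctsg.

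Cell division genes stood higher in deficient basophils as groups. Of 46 tested genes of the G2 and M phases 45 had a positive change, with a median of 0.68 (camera adjusted p = 3.27e-23). Birc5 was called over all genes, and 15 rose when adjusted over the list alone. Histone genes had 61 of 62 positive changes and a median of 0.78 (adjusted p = 4.2e-41), with 0 called over all genes and 47 adjusted over the list alone; some of these genes are near-identical copies whose reads cannot be assigned with certainty. S phase genes had 40 of 43 positive changes and a median of 0.41 (adjusted p = 6.04e-11), with 0 called over all genes and 3 adjusted over the list alone. With an estimated correlation the adjusted p was 0.715 for the G2 and M and histone lists and 0.779 for the S phase list. Members not called over all genes included Cdk1 (1.15 ± 0.23), Ccnb2 (1.19 ± 0.24), Tpx2 (1.08 ± 0.22), Rrm2 (1.25 ± 0.25) and H3c8 (1.09 ± 0.19), with adjusted p from 0.155 to 0.215. Fen1 (2.02 ± 0.47, adjusted p = 0.261) was called without the first control basophil library (2.86, adjusted p = 0.0128). Without the second deficient basophil library the median was 0.35 for G2 and M and 0.11 for S phase genes, and without the first 1.04 and 0.70. The second library thus carried most of the S phase difference. The levels stayed below those of pre-Baso: Cdk1 had 24.3 ± 4.15 TPM in control pre-Baso, 2.66 ± 0.945 in control basophils and 6.98 ± 0.259 in deficient basophils (SD, n = 2).

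Of the lists of basophil function, 4 stood lower in deficient basophils, while cytokines (adjusted p = 0.157), granule proteases (adjusted p = 0.446) and lipid mediator synthesis (adjusted p = 0.335) were not called. Cytokine and chemokine receptor genes had 3 of 29 positive changes and a median of -0.25 (adjusted p = 5.04e-05), with values of -0.70 ± 0.18 for the complement receptor gene C3ar1 and -0.82 ± 0.20 for Il7r. Interferon response genes had a median of -0.26 (adjusted p = 0.000449), adhesion genes -0.19 (adjusted p = 0.000875) and Fc epsilon RI signalling genes -0.16 (adjusted p = 0.00186). With an estimated correlation each of these 4 lists had adjusted p = 0.779. In these lists 0 members were called over all genes and 0 adjusted over the list alone. The interferon call ended without the second deficient basophil library (adjusted p = 0.149), and its median was -0.17 without the first control basophil library.

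The identity list fell in basophils with 8 of 28 positive changes and a median of -0.17 (camera adjusted p = 0.00212, and adjusted p = 0.818 with an estimated correlation). Mcpt8 was again the 1 called member over all genes and over the list alone, and camera was not run without Mcpt8. The list call ended without the second control basophil library (median -0.15). Its members Cd7 (-0.99 ± 0.28, adjusted p = 0.328), Fcer1a (-0.80 ± 0.27, adjusted p = 0.421) and Prss34 (1.06 ± 0.29, adjusted p = 0.324) were not called. The interleukin gene Il4 had 101.2 ± 2.58 TPM in control and 72.1 ± 9.39 TPM in deficient basophils (-0.49 ± 0.15, adjusted p = 0.374).

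Genes of the unfolded protein response stood higher in deficient basophils (median 0.21, adjusted p = 0.00447, and adjusted p = 0.818 with an estimated correlation), as did granulocyte progenitor genes (median 0.23, adjusted p = 0.00869, and adjusted p = 0.779 with an estimated correlation). The progenitor list includes Ctsg, its 1 called gene over all genes and over the list alone, and Mpo (1.10 ± 0.31, adjusted p = 0.335). Ctsg lies 0.0177 Mb from Mcpt8. The mean log2(TPM + 1) of the progenitor list overlapped between genotypes, with 3.62 and 3.24 in control and 3.60 and 3.82 in deficient basophil libraries. The first call ended without the second deficient basophil library (median 0.07, adjusted p = 0.138). Its median was 0.12 without the second control and 0.33 without the first deficient basophil library. The progenitor call ended without the second control basophil library (median 0.02, adjusted p = 0.229). There the median was 0.47 without the first control, 0.48 without the first deficient and 0.14 without the second deficient one. In all 13 lists were called, 6 higher and 7 lower. The remaining ones were nuclear respiratory chain genes (median 0.10, adjusted p = 0.011, and adjusted p = 0.86 with an estimated correlation), clock genes (median -0.22, adjusted p = 0.0131, and adjusted p = 0.715 with an estimated correlation) and eosinophil markers. The clock list includes Nfil3, the removed gene, and camera was not run without it. Without the second control basophil library the respiratory chain (median -0.0005, adjusted p = 0.334) and clock (adjusted p = 0.0607) calls ended. The medians without the first one were 0.20 and -0.13, and the respiratory chain had 0.06 without the second deficient basophil library.

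Eosinophil markers differed between libraries more than between genotypes. Prg2, the eosinophil major basic protein gene, had 2354 TPM in the first control basophil library and 19.4 in the second, and 152 and 18.9 TPM in the deficient basophil libraries. The eosinophil list had a median of -0.94 in the genotype comparison of basophils (adjusted p = 0.00186, and adjusted p = 0.779 with an estimated correlation), and without the first control basophil library the median was 0.87 (adjusted p = 0.343). Without the second deficient basophil library it was -0.48 (adjusted p = 0.19), and without the second control and first deficient ones -3.12 and -1.68. Cd74, an antigen presentation gene, had 333 and 7.32 TPM in the control and 302 and 14.1 TPM in the deficient basophil libraries, so the first library of each basophil group stood apart.

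**Figure D2:**
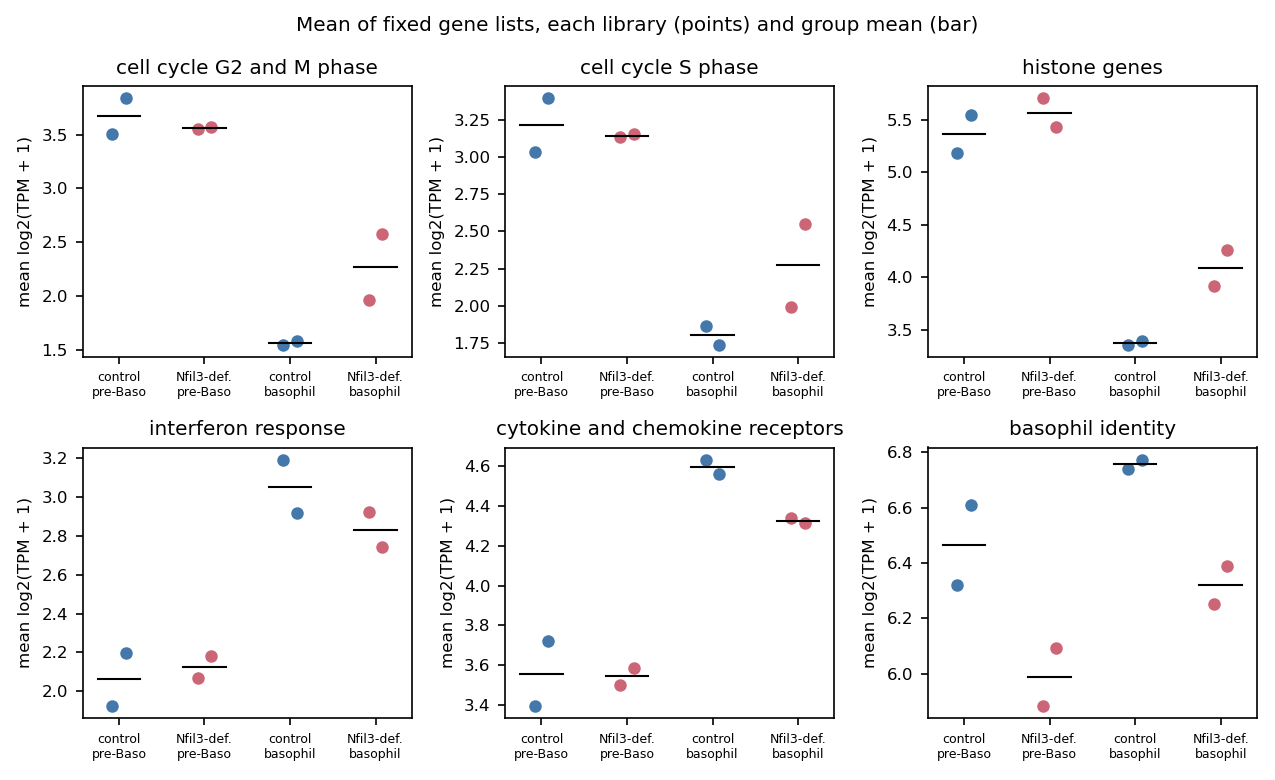
Mean log2(TPM + 1) of the members of fixed gene lists in each library (points, 2 per group) and per group (bars). Scores of the G2 and M phase and histone lists are highest in pre-Baso, lowest in control basophils and in between in deficient basophils.

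Averaged over both populations, 11 genes were called between genotypes, 6 higher and 5 lower, with 931 at an unadjusted p under 0.05. Besides Mcpt8 (-9.32 ± 0.17), Rnase12 (-4.16 ± 0.13), Nfil3 (-3.05 ± 0.18), Rprl3 (5.84 ± 0.27) and Ctsg (1.74 ± 0.15), Rpph1 fell (-1.63 ± 0.16, adjusted p = 0.00813) and Lgals3 (0.75 ± 0.10, adjusted p = 0.0492) and the nucleotide receptor gene P2ry2 (0.96 ± 0.12, adjusted p = 0.0492) rose. Lgals3 and P2ry2 lost their calls when any of the 8 libraries was left out (adjusted p from 0.0807 to 0.208 and from 0.0777 to 0.242). Rpph1 lost it without the first control, second control or second deficient pre-Baso library (adjusted p = 0.0734, 0.0807 and 0.0606), and without either deficient pre-Baso library 7 genes were called in all. Without a filter on low values the calls of Ctsg and Rpph1 ended (adjusted p = 0.112 and 0.114). Rpph1 and Rprl3 share sequence, so the split of their reads is uncertain, and 6 of the 11 genes, Mcpt8 included, lie within 10 Mb of Mcpt8.

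In this mean comparison 12 lists were called, 5 higher and 7 lower, with adjusted p of 0.761 or more with an estimated correlation. Histone genes had a median of 0.51 (camera adjusted p = 1.18e-41), with 0 members called over all genes and 46 adjusted over the list alone, and G2 and M genes had a median of 0.25 (adjusted p = 4.31e-12). This G2 and M value is the median over genes of changes averaged over both populations. The list medians were 0.68 in basophils and -0.11 in pre-Baso, where 7 of 46 were positive and camera did not call the list (adjusted p = 0.212). In the mean comparison the G2 and M median was 0.11 without the second and 0.49 without the first deficient basophil library. The basophil identity list had a median of -0.13 (adjusted p = 0.00076) with Mcpt8 as its 1 called member. The identity median was -0.20, -0.05 and -0.08 without the first control, second control and first deficient pre-Baso library.

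The genotype effect was also compared between the populations. No gene was called by limma for a difference of the effect, with 689 genes at an unadjusted p under 0.05 where 626 would be expected by chance. The genes with the smallest p included Birc5 (2.71 ± 0.41, adjusted p = 0.536), Samhd1 (-1.30 ± 0.26, adjusted p = 0.668) and Mcpt8 (1.75 ± 0.34, adjusted p = 0.668). Across genes, which are not independent replicates, the genotype effects in the 2 populations correlated with r = 0.170, or 0.113 without Nfil3 and Mcpt8.

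The comparison of basophils with pre-Baso in control mice asks what changes as the cells mature. Proliferation genes fell: Birc5 from 78.5 ± 15.9 to 2.55 ± 0.07 TPM (SD, n = 2; log2 change -4.47 ± 0.29), Top2a, the DNA topoisomerase of dividing cells, from 67.0 ± 11.6 to 4.96 ± 2.82 TPM (-3.59 ± 0.43), and Stmn1 from 64.8 ± 5.47 to 6.36 ± 1.43 TPM (-3.17 ± 0.25). Among the genes with the largest rise, Cd7, a surface protein, rose from 13.1 ± 4.10 to 241 ± 5.99 TPM (4.12 ± 0.28), the chemokine gene Ccl6 from 180 ± 50.6 to 1719 ± 9.54 TPM (3.28 ± 0.18), Samhd1 from 4.48 ± 0.48 to 62.7 ± 3.68 TPM (3.54 ± 0.18) and C3ar1 from 12.2 ± 1.69 to 93.9 ± 4.57 TPM (2.85 ± 0.18). Nfil3 rose 3.01-fold (1.47 ± 0.25, adjusted p = 0.00506), a call that ended with a pseudocount of 0.1 (adjusted p = 0.173) and with protein-coding genes only (adjusted p = 0.0863). In all 2832 genes were called, 1576 higher and 1256 lower in basophils (1536 and 1754 after median-of-ratios scaling), with adjusted p from 0.00023 to 0.00125 for Birc5, Top2a, C3ar1 and Cd7 and 4524 genes at an unadjusted p under 0.05. The count was 1397 (564 higher, 833 lower) and 1794 without the first and second control pre-Baso library. It was 1590 (690 higher, 900 lower) and 1870 without the first and second control basophil library, so the balance of directions was not stable.

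Cell cycle lists fell most. Of 46 G2 and M genes 43 fell over all genes and 45 adjusted over the list alone (median -2.21, camera adjusted p = 7.58e-32), among them Ccnb2 (-3.07 ± 0.24), Cdk1 (-2.80 ± 0.23), Ube2c (-3.08 ± 0.29) and Spc25 (-3.14 ± 0.34). Of 62 histone genes 60 fell, by both counts (median -2.12, adjusted p = 2.54e-44). Of 43 S phase genes 34 fell, and 37 adjusted over the list alone (median -1.43, adjusted p = 2.57e-20), among them Rrm2 (-2.85 ± 0.25), Tyms (-1.81 ± 0.21) and Fen1 (-3.24 ± 0.47). With an estimated correlation each of these 3 lists had adjusted p = 0.34. The replication and chromatin genes Rfc4 (-3.07 ± 0.44), Hmgn2 (-3.02 ± 0.45) and Asf1b (-2.93 ± 0.24) were also among the 12 with the lowest change.

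Granule and progenitor genes fell as well. Of 25 granulocyte progenitor genes 12 fell and 2 rose over all genes (12 and 3 adjusted over the list alone; median -0.87, camera adjusted p = 4.92e-05, and adjusted p = 0.378 with an estimated correlation), including Ctsg (-3.16 ± 0.21), Ms4a3 (-2.98 ± 0.26) and the myeloperoxidase gene Mpo (-2.83 ± 0.31). Among 16 granule genes 6 fell and 2 rose (6 and 3 adjusted over the list alone; median -0.30, adjusted p = 0.0257, and adjusted p = 0.478 with an estimated correlation): Mcpt8 (-2.59 ± 0.24), Prss34 (-2.67 ± 0.29) and Cpa3 (-1.78 ± 0.20) fell, and the lysosomal protease gene Ctsd (1.22 ± 0.12) rose. The granule call ended without the second control basophil library (median -0.09, adjusted p = 0.121). The granule median was -0.45, -0.15 and -0.61 without the first control pre-Baso, second control pre-Baso and first control basophil library. Genes of the unfolded protein response fell, 15 of 32 with 1 higher (17 and 2 adjusted over the list alone; median -0.52, adjusted p = 1.09e-06, and adjusted p = 0.423 with an estimated correlation), with Sdf2l1 at -2.48 ± 0.26 and Manf at -1.62 ± 0.23.

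Cytokine, receptor and signalling genes rose. Of 14 cytokine genes 10 rose (11 adjusted over the list alone; median 1.14, camera adjusted p = 1.41e-05, and adjusted p = 0.34 with an estimated correlation), led by Ccl6, Ccl4 (2.48 ± 0.23), Ccl9 (2.20 ± 0.17) and Il4 (1.30 ± 0.15). Il13 (0.80 ± 0.22, adjusted p = 0.033) lost its call when any library but a deficient basophil one was left out, with adjusted p from 0.0505 to 0.148. Of 29 receptor genes 16 rose and 1 fell (19 and 1 adjusted over the list alone; median 0.92, adjusted p = 9.44e-08, and adjusted p = 0.34 with an estimated correlation), including C5ar1 (2.41 ± 0.18), Il7r (2.55 ± 0.20) and the interleukin 3 receptor gene Csf2rb2 (1.66 ± 0.18). Of 37 Fc epsilon RI signalling genes 14 rose and 1 fell (20 and 1 adjusted over the list alone; median 0.59, adjusted p = 2.13e-05, and adjusted p = 0.423 with an estimated correlation). The kinase gene Syk (0.93 ± 0.17) and the adaptor genes Gab2 (1.24 ± 0.20) and Lat2 (0.85 ± 0.14) rose. Fcer1a fell (-1.29 ± 0.27, adjusted p = 0.0109), a call that ended without the first control pre-Baso library (-1.11). The populations were sorted by staining for the chain that Fcer1a encodes, so its fall is not independent of the sort.

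Immediate early genes rose, 17 of 25 (18 adjusted over the list alone; median 0.84, camera adjusted p = 4.37e-08, and adjusted p = 0.34 with an estimated correlation), with Zfp36 at 2.51 ± 0.29 and Junb at 1.97 ± 0.24. Interferon response genes rose, 17 of 33 with 1 lower (23 and 1 adjusted over the list alone; median 0.84, adjusted p = 2.72e-08, and adjusted p = 0.34 with an estimated correlation), led by Samhd1, Slfn2 (2.78 ± 0.15) and Rtp4 (1.75 ± 0.20). Adhesion genes rose, 16 of 34 (19 with 1 lower adjusted over the list alone; median 0.48, adjusted p = 8.26e-05, and adjusted p = 0.473 with an estimated correlation), with Itgb3 at 1.65 ± 0.17 and Cd44 at 1.44 ± 0.20. Of 39 lineage transcription factors 12 rose and 2 fell (13 and 2 adjusted over the list alone; median 0.37, adjusted p = 0.00709, and adjusted p = 0.486 with an estimated correlation), with a median of 0.25 without the first control basophil library, including Spi1 (1.08 ± 0.13), Klf2 (1.98 ± 0.29) and Bhlhe40 (1.28 ± 0.19). The apoptosis list was not called (adjusted p = 0.343) and held genes of both directions: Bcl2 fell (-1.44 ± 0.19), while Mcl1 (0.84 ± 0.15) and Fas (1.61 ± 0.23) rose.

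Of the other lists, clock genes rose, 6 of 13 with 1 lower (8 and 1 adjusted over the list alone; median 0.64, adjusted p = 0.00954, and adjusted p = 0.34 with an estimated correlation). Nuclear respiratory chain genes fell, 19 of 75 with 2 higher by both counts (median -0.39, or -0.25 without the second control basophil library, adjusted p = 9.97e-08, and adjusted p = 0.486 with an estimated correlation), as did cholesterol synthesis genes, 6 of 19 by both counts (median -0.45, adjusted p = 0.000312, and adjusted p = 0.473 with an estimated correlation). Of 80 ribosomal protein genes 19 rose and 4 fell (20 and 4 adjusted over the list alone; median 0.19, adjusted p = 0.0232, and adjusted p = 0.672 with an estimated correlation), a call that ended without the first control basophil library (adjusted p = 0.0612), with medians of 0.12 and 0.30 without the first and second control pre-Baso library. Of 13 mitochondrially encoded genes 1 was called lower over all genes and 0 adjusted over the list alone (median -0.23, adjusted p = 0.0258, and adjusted p = 0.595 with an estimated correlation), a call that ended without the second control pre-Baso (median -0.07, adjusted p = 0.224) or second control basophil library (median -0.09, adjusted p = 0.154). In all 21 lists were called, 12 higher and 9 lower, and the basophil identity list was not (12 of 28 genes higher and 5 lower, 13 and 5 adjusted over the list alone; adjusted p = 0.0643).

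Markers of 3 other cell types were also higher in control basophils, while dendritic cell (adjusted p = 0.091), B and plasma cell (adjusted p = 0.0949), erythroid (adjusted p = 0.12) and megakaryocyte markers (adjusted p = 0.12) were not called. Of 28 neutrophil markers 14 rose and 2 fell (20 and 2 adjusted over the list alone; median 1.02, adjusted p = 0.000312, and adjusted p = 0.486 with an estimated correlation), with Cxcr2 at 2.32 ± 0.27 and a median of 0.64 without the first control basophil library. Of 22 monocyte and macrophage markers 7 rose (7 adjusted over the list alone; median 1.27, adjusted p = 0.000283, and adjusted p = 0.486 with an estimated correlation), with a median of 0.47 without that library. Of 12 eosinophil markers 4 rose (4 adjusted over the list alone; median 1.79, adjusted p = 0.00134, and adjusted p = 0.473 with an estimated correlation), with Siglecf at 1.87 ± 0.25 and Ccr3 at 1.70 ± 0.18, and without the first control basophil library the median was 0.21 (adjusted p = 0.131) and without the second 4.12. The neutrophil gene S100a8 had a mean of 273 TPM in control pre-Baso and 618 in control basophils, and the macrophage gene Lyz2 had 139 and 470 TPM. For Lyz2 the log2 change of 1.59 ± 0.45 (adjusted p = 0.0357) was 0.90 without the first control basophil library (adjusted p = 0.148). Its call also ended without any pre-Baso library (adjusted p from 0.0555 to 0.167).

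In Nfil3-deficient mice the change from pre-Baso to basophils had the same direction for most of these genes. Cd7 rose from 13.01 ± 5.28 to 120 ± 3.1 TPM (SD, n = 2; log2 change 3.17 ± 0.28), Ccl6 from 269 ± 28.9 to 1391 ± 60.3 TPM (2.37 ± 0.18), and C3ar1 (2.33 ± 0.18), C5ar1 (1.99 ± 0.18), Adam8 (2.36 ± 0.25), Gstm1 (2.31 ± 0.13), Mapk12 (2.36 ± 0.17) and Zfp36 (2.28 ± 0.29) rose with them. Cell cycle genes fell, among them Ccnb1 (-1.98 ± 0.24), Cenpw (-2.28 ± 0.40), Sapcd2 (-2.10 ± 0.34) and Top2a (-1.95 ± 0.43). The progenitor gene Ctsg (-1.82 ± 0.21) and the basophil genes Fcer1a (-1.65 ± 0.27), Prss34 (-1.49 ± 0.29) and Cpa3 (-1.38 ± 0.20) fell as well. As in control mice, the fall of Fcer1a is not independent of the sort. Sdr39u1 fell too (-2.08 ± 0.38), while in control mice it was not called and had a positive value (0.55 ± 0.38, adjusted p = 0.337). With only the compared groups fitted its call in deficient mice ended (limma adjusted p = 0.0563). No gene was called for a difference of the genotype effect between populations, so a difference between genotypes is not shown for Sdr39u1. In all 1363 genes were called, 849 higher and 514 lower, with 3517 at an unadjusted p under 0.05.

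These calls in deficient mice rest on few libraries. Without the first deficient pre-Baso library 19 genes were called, 19 higher and 0 lower, and 27 of 38 called genes picked for naming in this contrast lost their call. Without the second deficient pre-Baso library 592 were called, and without the first and second deficient basophil library 228 and 658, the latter with 259 higher and 399 lower. After median-of-ratios scaling 893 genes were higher and 1030 lower, and after quantile normalization 986 and 1029, so the balance of directions depends on the scaling and on single libraries. By camera 24 lists were called, 16 higher and 8 lower. Histone genes had 57 of 62 lower (61 adjusted over the list alone; median -1.58, adjusted p = 6.09e-52), G2 and M genes 37 of 46 (42 adjusted over the list alone; median -1.32, adjusted p = 3.19e-30), and immediate early genes 15 of 25 higher (16 adjusted over the list alone; median 0.86, adjusted p = 3.15e-09), each with adjusted p = 0.371 with an estimated correlation. S phase genes had 16 of 43 lower (29 adjusted over the list alone; median -0.87, or -0.56 without the first deficient basophil library, adjusted p = 9.9e-18, and adjusted p = 0.408 with an estimated correlation).

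Markers of other cell types were also called higher in deficient basophils than in deficient pre-Baso: neutrophil (median 0.82, adjusted p = 0.00027), monocyte and macrophage (1.15, adjusted p = 0.00047), eosinophil (1.10, adjusted p = 0.0145), dendritic cell (1.16, adjusted p = 0.0385) and megakaryocyte markers (0.54, adjusted p = 0.0415). The adjusted p with an estimated correlation was 0.46 for the first 3, 0.575 for dendritic cell and 0.45 for megakaryocyte markers. Without the first deficient basophil library the monocyte (median 0.50, adjusted p = 0.192), eosinophil (0.42, adjusted p = 0.171) and dendritic cell calls (0.49, adjusted p = 0.854) ended and the neutrophil median was 0.51. The dendritic cell call also ended without the first control, second control or second deficient pre-Baso library (adjusted p = 0.0592, 0.0594 and 0.0658). The megakaryocyte call ended without the second deficient pre-Baso, first control basophil, second control basophil or second deficient basophil library (adjusted p = 0.0743, 0.0531, 0.0536 and 0.111).

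The changes of both genotypes, which share no library, were set side by side. Across genes, r was 0.778 and 714 genes were called higher and 461 lower in both, against 107 and 51.6 for independent lists, with 0 called in opposite directions. Among genes called higher in control mice the median log2 change was 0.92 there and 0.69 in deficient mice. Among those called lower it was -1.10 and -0.68. Genes chosen in 1 genotype regress in the other, and among genes called lower in deficient mice the medians were -1.51 in control and -1.11 in deficient mice. For genes called higher in deficient mice they were 0.99 and 0.94.

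**Figure D3:**
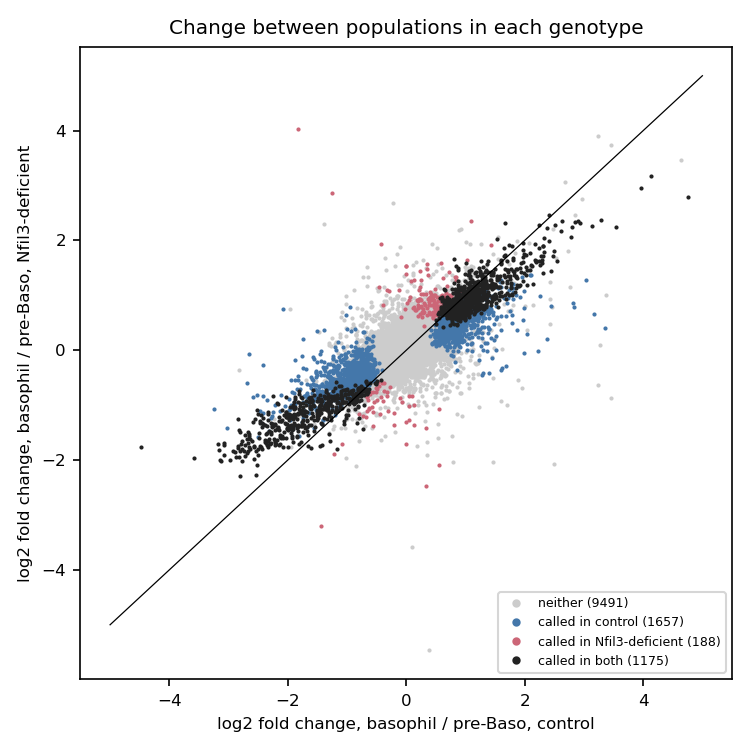
Log2 change from pre-Baso to basophils in control mice (horizontal axis) and in Nfil3-deficient mice (vertical axis) for 12511 tested genes (points), coloured by the genotype in which limma called them; the line marks equal change. Genes called in both genotypes (714 higher, 461 lower) lie on the same side of 0 in each.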

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

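The lists below were picked out by a rule fixed beforehand, and no tests in this part were chosen after the result was seen. In 11 of the 29 lists the genotype effect differed between basophils and pre-Baso by camera. For each gene the log2 effect in pre-Baso was subtracted from that in basophils, with 2 libraries per group. Values are medians of these differences over the genes of a list, not differences of the list medians. The effect was higher in basophils for G2 and M genes (0.83, adjusted p = 2.46e-19), histone genes (0.54, adjusted p = 1.88e-16), S phase genes (0.51, adjusted p = 6.89e-09), granulocyte progenitor genes (0.41, adjusted p = 0.00193), the unfolded protein response (0.38, adjusted p = 0.000107) and cholesterol synthesis (0.20, adjusted p = 0.0342). It was lower for cytokines (-0.36, adjusted p = 0.0014), interferon response genes (-0.28, adjusted p = 0.000112), receptors (-0.17, adjusted p = 0.000524), ribosomal proteins (-0.15, adjusted p = 8.32e-06) and eosinophil markers (-0.69, adjusted p = 0.019).

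With an estimated correlation each of the 11 lists had adjusted p = 0.788, and 0 single genes were called for this difference by limma. The ribosomal call ended without the first deficient pre-Baso library (adjusted p = 0.139) and the progenitor call without the second (adjusted p = 0.0908). For eosinophil markers the median was 0.96 without the first control basophil library (adjusted p = 0.218), and the call also ended without the second control pre-Baso (adjusted p = 0.242) or second deficient basophil library (adjusted p = 0.311). The cholesterol call ended without the second library of any of the 4 groups (adjusted p from 0.0847 to 0.198).

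Single libraries also moved medians whose calls held. Without the second deficient basophil library the value was 0.52 for G2 and M, 0.23 for S phase and 0.19 for progenitor genes, and without the first it was 0.78 for S phase and -0.24 for cytokines. Without the first control basophil library it was -0.17 for cytokines, -0.14 for interferon response and 0.69 for progenitor genes, and without the second 0.20 for progenitor genes and 0.25 for the unfolded protein response. Without the first control pre-Baso library it was -0.12 for interferon response, -0.08 for ribosomal and 0.35 for cholesterol genes, and without the second 0.34 for histone, 0.23 for unfolded protein response and -0.27 for ribosomal genes. Without the second deficient pre-Baso library it was -0.19 for cytokines, -0.14 for interferon response and -0.25 for ribosomal genes, and without the first 0.31 for cholesterol genes. For receptors it ranged from -0.35 without the second to -0.08 without the first control pre-Baso library, and it was -0.31, -0.28 and -0.27 without the second control, first deficient and second deficient basophil library. Eosinophil markers had -2.99 and -1.46 without the second control and first deficient basophil library.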

How the results depend on the processing

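Counts of called genes moved with the handling of low values. Without a filter on low values they were 23 in pre-Baso, 18 in basophils and 5 for their mean (against 8, 7 and 11), and 1516 and 298 for maturation in control and deficient mice (against 2832 and 1363). A pseudocount of 0.1 gave 16 in basophils, 19 for the mean and 2 for the difference of effects (against 0). A filter at a TPM of 5 gave 17 for the mean and robust moderation 19, while removing mitochondrial and ribosomal protein genes gave 7. Rescaling to protein-coding genes, added after the data were seen, gave 5 in pre-Baso, 18 in basophils and 2 for the difference. Fitting only the compared groups gave 3 in pre-Baso, 4 in basophils and 562 for maturation in deficient mice, and was not run for the mean and the difference, whose groups are all 8 libraries. For each of these changes the cause was not tested. The interaction value of Nfil3 changed sign, from -0.77 to 0.53 with a pseudocount of 0.1 and to 0.076 with protein-coding genes only, which follows from the weight that each scale gives to values near 0.

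With a replicate block 7 genes were called for the mean, and Nfil3 kept its difference of -3.05 with an exact permutation p of 0.0556, which is the smallest p that permuting within replicate numbers allows. In pre-Baso the block ended the Lgals3 call (limma adjusted p = 0.128) and added a call of Rpph1 (adjusted p = 0.0324). For the mean it ended the calls of P2ry2 and Lgals3 (adjusted p = 0.112 and 0.121). Whether replicate numbers pair the samples stayed open: deviations of replicates correlated between groups with r from -0.054 to 0.202 across genes, which are not independent replicates. The highest r was between the 2 basophil groups, in both of which the first library had the higher monocyte marker score (3.64 against 2.21 and 3.57 against 2.35).

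Calls of lists depended on the correlation assumed between genes. An estimated correlation left 0 lists called in each of the 6 comparisons. A test of list mean scores, added later, left 0 in pre-Baso, 0 in basophils, 0 for the mean and 0 for the difference. For maturation it left 15 in control mice (against 21) and 10 in deficient mice (against 24). Median-of-ratios scaling gave 6 in pre-Baso (against 10). The cause was not tested for these counts.

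Leaving out each of the 8 libraries in turn gave 5 to 9 genes in pre-Baso, 6 to 17 in basophils, 7 to 11 for the mean, 1397 to 2651 and 19 to 1237 for maturation in control and deficient mice and 0 to 2 for the difference. Called lists ranged in the same order from 6 to 13, 13 to 17, 10 to 17, 20 to 23, 19 to 24 and 10 to 16, and the Nfil3 difference from -3.33 to -2.79. The cause was not tested. Of 3259 values of single named genes, many of them never called, 182 lost a call, 9 gained one, 2 changed sign and 3066 had none of these. With 2 libraries per group and 18.7% to 22.4% of TPM in protein-coding genes, small changes of weakly expressed genes may have been missed, which was not tested.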

Other observations

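Of the tests in this section only the window correlation was fixed beforehand, and the others were chosen after the result was seen. Control pre-Baso held more Fcer1a, Prss34, Cpa3 and Mcpt8 RNA than control basophils, while Il4, Ccl6 and receptor genes were higher in basophils. Fcer1a had 852 ± 152 TPM in control pre-Baso and 352 ± 102 TPM in control basophils (SD, n = 2), the same order as the surface staining by which they were sorted.

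All tests of the first pattern but the window correlation were chosen after the result was seen. Of the 11 genes called in the mean genotype comparison, 6, Mcpt8 included, lie within 10 Mb of Mcpt8 on chromosome 14, while Nfil3 is on chromosome 13. With called genes left out, the share under an unadjusted p of 0.01 was 5.24 times as high inside the window as outside (14 of 154 against 214 of 12343), which is in line with a linked segment, such as an altered Mcpt8 locus carried by the deficient mice. The window correlation of the genotype effects, the test fixed beforehand, failed: with called genes left out, r was 0.240 across genes, below the 95th percentile of 0.436 over windows. Of the 106 other windows 13 were as high, and their median was 0.076. With the called genes, picked for their effects, r was 0.777 over 160 genes, so the linked segment stays a hypothesis. The other basophil identity genes had a median of -0.12, which speaks against a full replacement of basophils by other cells. All cells were sorted by CD200R3 and IgE receptor staining, and this median could not reveal a partial replacement. The summed RNase P genes changed by a log2 of -1.26, less than Rpph1 alone (-1.63). Reads shifted between the summed copies thus did not account for the whole fall of Rpph1. They may account for part of it and for the rise of Rprl3. Reads placed outside the summed genes were not counted, so the sum cannot exclude shared reads.

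Tests of the second pattern were all chosen after the result was seen. Cell division and histone lists were called higher in deficient basophils by camera, but not with an estimated correlation (adjusted p = 0.715 for G2 and M and histone, 0.779 for S phase), and 1 member, Birc5, was called over all genes. If pre-Baso RNA were mixed in, the fraction should be alike for all genes of a library. Over both deficient libraries it was 0.103 to 0.266 from genes high in pre-Baso and 0.244 to 0.450 from genes high in basophils, a difference of medians of 0.185. These pooled ranges overlapped, so the test as set could not tell. Within each library the medians did not overlap: 0.103 and 0.106 against 0.244 and 0.407 in the first, 0.264 and 0.266 against 0.332 and 0.450 in the second. With the second control as baseline, however, the quartiles of genes high in basophils (-0.427 to 0.483 and -0.024 to 0.575) spanned the lower medians, so no conclusion is drawn. The G2 and M score difference of 0.707 was 0.400 without the second deficient basophil library, so 1 library alone did not produce it, while the S phase median fell from 0.41 to 0.11 without that library. It was 0.710 after median-of-ratios scaling, which moved the median of all genes only from -0.01 to 0.01 and so could not have removed the difference. Delayed maturation may account for the pattern, a hypothesis that protein markers of division in sorted cells would test.

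Tests of the third pattern were chosen after the result was seen. The 8 libraries were split into 4 and 4 in other ways, with population as a term, and 34 splits could be fitted. Under this model the real split called 6 genes and the highest other split 3, so 1 of 34 was as large, the real one itself. Only 18 splits are balanced within the populations, too few for a share under 0.05, and there the highest other count was also 3.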
